A study of Homo sapiens with 48 samples.

How the data were processed

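The measurements were gene expression profiles of U2OS cells, a human osteosarcoma line, in a clone that stably carries wild-type rat glucocorticoid receptor alpha. RNA was hybridised to Illumina HT-12 v4 bead arrays, 48 in all on 6 slides. Per the labels, the arrays form 12 groups of 4: cells with no siRNA (NI), with a nonspecific siRNA (siNS) or with 1 siRNA against Hic-5 (siHic5_2), each after 0, 2, 4 or 24 h of dexamethasone, a synthetic glucocorticoid. Transfected wells received 60 pmol of siRNA, and all wells were harvested at the same time, so that the hormone was added at different times after transfection. The replicate numbers 1 to 4 come from the labels. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may in part be technical.

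The deposited raw table holds an unnormalized bead intensity and a detection p-value for each probe and array, per the file headers. It lists 47323 probes, 883 control rows, 4 repeats of control rows and 0 columns of no sample. A second deposited table holds the authors' processed log2 values of the same probes. Per the submitters' processing notes, R 2.15.3 and limma 3.14.4 were used; the normalization is not given in the sources used here. The ranks of the processed values matched the own-named raw intensity column on 48 of 48 arrays, with array medians of 5.422 to 5.425. The scale of that table was read from its values, which differed from those computed here by 0.263 or less on the log2 scale, and its values are not centred by gene.

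The deposited detection p-values stand under the wrong array names. None of the intensity columns had the ranks its own-named p column implies (rank correlation -0.261 to -0.175), while 32 of 48 matched the p column of another array. Detection p-values were therefore recomputed on each array as the share of its 770 negative-control probes at or above a probe's intensity. For the 32 matched columns the recomputed values lay within 0.00195 of the deposited ones in 100.0% of 48206 probes and control rows, with a largest gap of 0.0013.

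Intensities were normalized with neqc in limma 3.58.1 (R 4.3.3): a normexp background correction with parameters inferred from the recomputed detection p-values, an offset of 16, quantile normalization and log2. A probe was kept if its detection p was under 0.01 on at least 4 of the 48 arrays, which left 20912 probes. Gene names came from the platform annotation given with the data: 30113 probes had 1 symbol, 8 had several and 17202 were unnamed here. Through gene identifiers 0 symbols changed, and 39 identifiers were not in the reference table used. Of the kept probes, 15904 had 1 gene, and each gene was represented by its probe with the highest mean over all arrays, giving 11886 genes. Where the kept probes of a named gene disagreed in sign, or by over 1 on the log2 scale for a printed difference, this is stated; a bound rests on the probe used for the gene.

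Median array intensity was 133.6 to 193, and 15009 to 18145 probes per array (31.7 to 38.3%) were above background. The number of arrays, 4 per group, limits the precision: the median standard error was 0.202 on the log2 scale for a difference of 2 groups and 0.285 for an interaction. A gene with detection p of 0.01 or more on every array of a group was not above background there. Its fold is given as a bound, the brighter group's mean over the mean of, per array, the higher of the lowest signal above background and the gene's own value. No fold is given where that bound is under 1, and no size for an interaction in which a group was not above background.

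A single limma model of 12 group means was fitted over all 48 arrays, with 36 residual degrees of freedom, and p-values were adjusted per contrast by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. There were 17 contrasts: siHic5_2 minus siNS at each of 4 times, each hormone time minus 0 h in siNS and in siHic5_2, the difference of the hormone response between siHic5_2 and siNS and between siNS and NI at each hormone time, and siNS minus NI over all times. The hormone responses in NI were fitted besides, to choose genes. The interaction was also summarised over genes chosen by their hormone response in NI arrays, which enter neither side of it, because choosing genes in siNS arrays pulls the interaction towards weaker responses. The Hic-5 level had an exact permutation test besides.

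In all, 21 gene lists were fixed from general knowledge: glucocorticoid-induced genes, inflammatory and AP-1 genes, circadian clock, cell cycle, focal adhesion, TGF-beta/SMAD targets, SRF/YAP and contractile genes, interferon response, p53 targets, ATF4 and unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, extracellular matrix and osteoblast genes, metallothioneins, receptor coregulators, Wnt targets, ribosomal proteins, reference genes, and markers of epithelial, blood and endothelial cells. They hold 441 genes, 412 of them on the array and 346 measured. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists of a contrast, and again with an estimated correlation; counts of list members are also given adjusted over the list alone, meaning that only the genes of that list enter the adjustment. The lists, the groups, the model, the rule for named genes and all alternatives but 4 were fixed before the data were examined.

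The genes named follow that rule. TGFB1I1 (the gene of Hic-5), its relatives PXN and LPXN, and NR3C1 were always named. For hormone responses and interactions so were FKBP5, TSC22D3, PER1, DUSP1, KLF9, ZBTB16, SGK1, NFKBIA, CEBPD, IL6, CXCL8 and CCL2. Each contrast added the 12 highest and 12 lowest changes among called genes detected on at least 1 array of each group, with no overlap between arrays where 2 groups were compared. It also added up to 3 bounds each way, up to 4 called members of each list, and the 8 largest called interactions, weaker and stronger, among genes chosen in NI. The text names a part of these, preferring genes whose call held with any 1 array left out; where it did not hold, the arrays are named.

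Whether replicate numbers pair the arrays was checked from the correlation of deviations from group means over genes. For the hormone responses same-numbered arrays correlated at 0.22 or more in siNS and 0.123 or more in siHic5_2, and each array correlated best with its own number, so the numbers pair these arrays; the pairing is seen in the data and is not stated in the labels. Same-numbered arrays correlated at 0.22 on the same slide and 0.2 on different slides, and differently numbered arrays at -0.026 and -0.072. Numbers did not pair siHic5_2 with siNS arrays.

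Alternatives were the authors' processed values, neqc with median scaling, no background correction, no probe filter or detection on 24 arrays, all probes uncollapsed, array weights, only the groups compared, NI in place of siNS, a fold of at least 1.5, the slide, the replicate number or both as blocks, an estimated correlation between list genes, and each array left out in turn. Added after seeing the data were neqc with the negative controls given directly, a replicate block within each transfection state, number 1 left out of all groups, and genes chosen in siHic5_2 arrays.

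The steps were tested on simulated data with the real means and spread of 11886 genes. For the 24 h knockdown contrast 34, 76, 96 and 98% of the 50 genes changed 1.5, 2, 3 and 4-fold were called, with 7 of 11686 unchanged genes. For the 24 h interaction these shares were 20, 48, 80 and 92%, with 5 unchanged genes. A shifted list was called and 0 of 19 unshifted lists were, which leaves lists of correlated genes untested. The choice of genes was simulated with independent arrays and, after seeing the data, with same-numbered arrays correlated as measured.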

Results

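Expression of 11886 genes was measured on 48 arrays, 4 for each combination of 3 transfection states and 4 hormone times. The series title and design ask how Hic-5, a focal adhesion protein that also acts as a coregulator of nuclear receptors, shapes the response of the glucocorticoid receptor to hormone. Groups are named by transfection state (NI, siNS or siHic5_2) and hours of dexamethasone. Median intensity of the arrays was 133.6 to 193 against negative-control medians of 114.4 to 161.1, and 31.7 to 38.3% of probes were above background. Within a group, the SD over genes of the difference between 2 arrays was 0.343 to 0.674 on the log2 scale. The first principal component (36.4% of the variance) set the 24 h arrays (scores 51.56 to 66.18) apart from all others (-37.53 to -3.71). The next (20.1%) set the 16 siHic5_2 arrays (-51.2 to -22.99) apart from the NI and siNS arrays (10.44 to 25.35).

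TGFB1I1, the gene of Hic-5, was 9.38% of its control level with siHic5_2 at 0 h and 9.93% at 2 h, and was not above background on any siHic5_2 array at 4 and 24 h, at least 10.6 and 5.71-fold lower there. Its log2 level at 0 h was 9.77 ± 0.25 in NI, 9.74 ± 0.18 in siNS and 6.33 ± 0.36 in siHic5_2 (SD, n = 4 each). At 24 h of hormone the TGFB1I1 levels were 8.71 ± 0.23, 8.68 ± 0.16 and 5.43 ± 0.51 (SD, n = 4 each). The differences at 0 and 2 h were -3.41 and -3.33 (SE 0.25), and limma adjusted p-values were 2.66e-13, 1.27e-12, 3.7e-15 and 4.62e-13 at the 4 times. The two-sided exact permutation p was 0.0286 at each time, the smallest that 70 splits of 8 arrays can give. The TGFB1I1 probe was above background on 2 and 1 siHic5_2 arrays at 0 and 2 h. Within the slides that held both groups at these times, TGFB1I1 differed by -3.98 to -2.87. A second TGFB1I1 probe was above background on at most 1 array of any group, with log2 means of 6.02, 5.80, 5.69 and 5.36 in siNS, 5.03, 5.35, 5.61 and 5.05 in siHic5_2 and 5.76, 5.83, 5.87 and 5.84 in NI, and was left out of the tests.

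**Figure D1:**
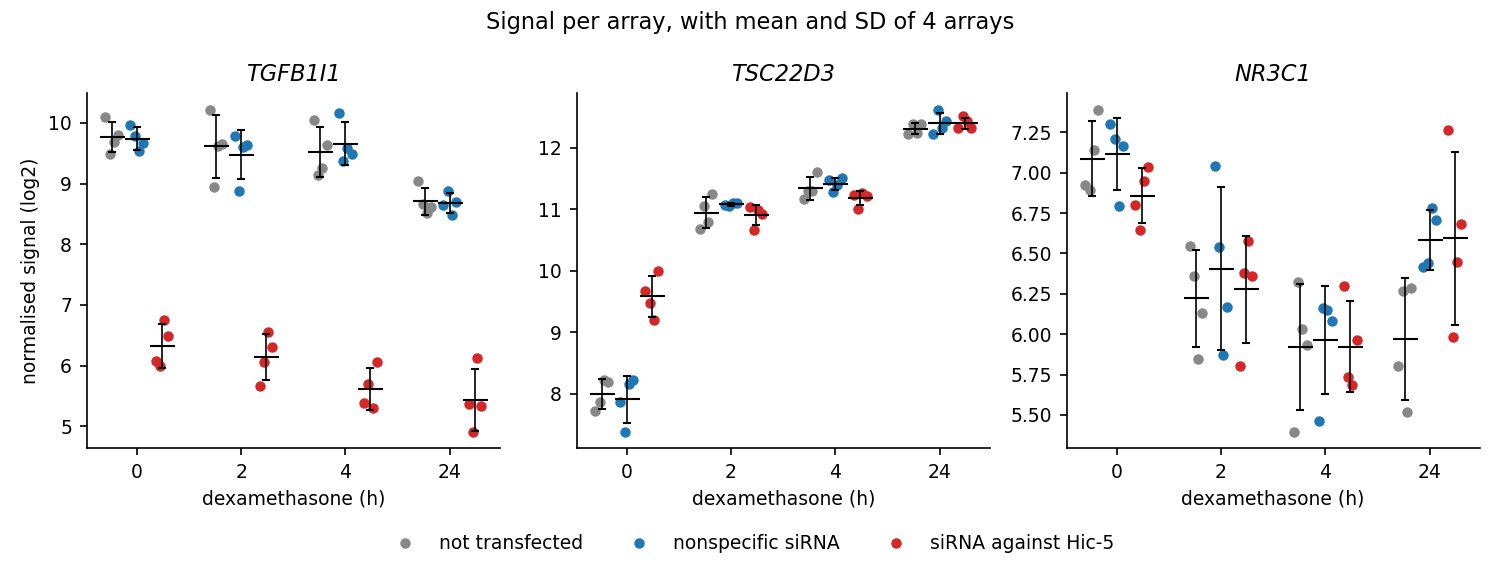
Log2 expression of TGFB1I1, TSC22D3 and NR3C1 on each of the 48 arrays by hours of dexamethasone, with group mean and SD, coloured by transfection state. TGFB1I1 lies at a mean of 6.33 or lower in all siHic5_2 groups and at 8.68 or higher in all siNS and NI groups, TSC22D3 starts at 9.58 in siHic5_2 and 7.90 in siNS and reaches 12.39 in both at 24 h.

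Between siNS and NI over all times, limma called 0 of 11886 genes, with 189 at an unadjusted p under 0.05. For the hormone response it called 0 as different at 2, 4 and 24 h, with 223, 120 and 147 at that unadjusted p. Same-numbered siNS and NI arrays correlated at 0.401 and were not paired in these tests, so 0 calls do not exclude an effect. Of the 21 lists, camera called the cell cycle list for the 24 h difference (median -0.20, adjusted p = 0.000157) with 0 genes called. With an estimated correlation it was not called (adjusted p = 0.987). With the replicate number as a block, which pairs siNS with NI arrays, camera also called the cholesterol synthesis list for siNS against NI (adjusted p = 0.00817, without the block 0.165). With the slide as a block camera called the glucocorticoid-induced list for the 2 h difference (median 0.23, adjusted p = 0.0404, without the block 0.14 and 0.862). Its response was larger in siNS than in NI.

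Cells with the siRNA against Hic-5 differed from siNS cells before any hormone. HMOX1, a heme-degrading stress enzyme, was higher by 3.94 (SE 0.52), the matrix protease MMP3 by 3.56 (0.39), the collagen-binding integrin subunit ITGA2 by 2.72 (0.27) and the matrix protease MMP9 by 2.70 (0.58). SUGCT (3.30), LY96 (2.76), the autophagy regulator DRAM1 (2.33), CST7 (2.32), PHACTR3 (2.29), CTHRC1 (2.26) and APOD (2.26) were also among the highest. The largest falls beside TGFB1I1 were in COL3A1, a fibrillar collagen (-3.28, SE 0.27), the sarcoplasmic reticulum peptide SLN (-2.88), FERMT2, an integrin activator (-2.84, SE 0.21), RRM2, a subunit of ribonucleotide reductase (-2.71), COL8A1 (-2.53, probes -2.53 to -1.38), FKBP3 (-2.47), TGFB2 (-2.45), HAPLN1 (-2.36) and OPA1, needed for mitochondrial fusion (-2.26). The limma adjusted p of these genes was at most 0.00169, that of LY96. RENBP, TCIM and HTN1 were not above background in siNS and were at least 7.97, 6.29 and 5.2-fold higher with siHic5_2; MOB3B, TRIL and LZTFL1 were at least 2.92, 2.35 and 2.28-fold lower.

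In all, limma called 3078 genes at 0 h (1638 higher, 1440 lower), 25.9% of those tested. At 2, 4 and 24 h it called 3069 (1704 and 1365), 3607 (1933 and 1674) and 3529 (1876 and 1653), or 25.8, 30.3 and 29.7%. Among these, 609 genes were higher and 636 lower at all 4 times, and 78 were called in both directions at different times. A change of at least 1.5-fold was seen in 2072, 2082, 2494 and 2424 of the called genes. With the slide as a block the counts were 3208, 2758, 3552 and 3642, and within single slides 96.1 to 99.9% of the genes called in a knockdown or hormone contrast had the same sign. These genes were called on the same arrays, and of the genes not called 62.9 to 80% had the same sign.

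The same leading genes recurred with hormone. HMOX1 was higher by 4.05, 4.19 and 2.84 at 2, 4 and 24 h, ITGA2 by 3.23 at 2 h, and MMP9 by 3.67 and 4.05 at 2 and 4 h. MMP3 was at least 13.1-fold higher at 2 h, where siNS cells had no array above background, and higher by 4.12 at 4 h. RRM2 differed by -2.82, -3.66 and -3.07 and FERMT2 by -2.58, -2.77 and -2.69. At 2 h smooth muscle actin ACTA2 (2.27) and LMO2 (2.26) were among the highest and KATNAL1 (-2.79) and CCP110 (-2.65) among the lowest. At 4 h RENBP (4.01) and GRAMD4 (2.66) stood beside BAIAP2L1 (-2.86). COL3A1 was at least 6.66-fold lower at 2 h and differed by -3.16 at 4 h. Limma adjusted p-values for these genes were at most 5.2e-05, that of HMOX1 at 24 h.

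At 24 h of hormone other genes led. SLCO2A1, a prostaglandin transporter, was higher by 4.27 (SE 0.42), the immediate-early gene ARC by 3.17 (0.43), HTRA4 by 3.13 (0.31), the MAP kinase phosphatases DUSP2 by 2.92 and DUSP5 by 2.68, APOD by 2.82 and beta-arrestin ARRB1 by 2.81 (probes 0.99 to 2.81). RP1L1, CD93 and SLC30A2 were at least 9.27, 7.13 and 6.98-fold higher. TEDDM1 differed by -5.23 (SE 0.34), the lipid droplet gene CIDEC by -3.94 (0.20; probes -3.94 to -1.56), the chemokine scavenger ACKR2 by -3.56, the neurotrophin receptor NTRK3 by -3.11, transglutaminase TGM2 by -2.72 (probes -2.72 to -1.34) and HAPLN1 by -2.64. KCNJ16 was at least 6.35-fold lower. The limma adjusted p was at most 6.01e-05, that of TGM2.

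Among relatives of Hic-5, PXN (paxillin) differed by 0.56, 0.20, 0.66 and 0.27 at 0, 2, 4 and 24 h, with limma adjusted p-values of 0.0431, 0.529, 0.0151 and 0.377. The PXN call at 0 h ended without siNS replicate 1, 3 or 4 or siHic5_2 replicate 1, 3 or 4. LPXN (leupaxin) differed by 1.87, 2.16, 1.88 and 0.40 (limma adjusted p = 0.0114, 0.00351, 0.00952 and 0.653). Its call at 0 h ended without siNS replicate 2 or siHic5_2 replicate 1, and all 3 calls ended when number 1 was left out of all groups. NR3C1, measured by a probe for the human glucocorticoid receptor gene in cells that carry the rat receptor, differed by -0.26, -0.13, -0.04 and 0.01, with limma adjusted p-values of 0.463 to 0.987.

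Genes of several groups moved with the siRNA against Hic-5. Of 18 p53 targets measured, 11, 12, 10 and 8 were higher at 0, 2, 4 and 24 h (12, 12, 10 and 8 adjusted over the list alone) and 0 were lower. They included the stress genes SESN1 (2.06 at 0 h) and GDF15 (at least 1.63-fold at 0 h), the death receptor FAS (at least 1.68-fold at 24 h), PHLDA3 (1.60 at 0 h) and the cell cycle inhibitor CDKN1A (1.56 at 24 h). Camera called the list at each time (adjusted p = 2.02e-08, 1.5e-06, 8.42e-05 and 0.00591), and at none with the correlation taken from the data (adjusted p = 0.0703, 0.219, 0.584 and 0.498 with an estimated correlation). Of 29 cell cycle genes 14, 13, 13 and 21 were lower (20, 21, 14 and 24 adjusted over the list alone) and 0 were higher, among them RRM2, the proliferation marker MKI67 (-1.29 at 0 h), the mitotic activator CDC20 (-1.25 at 0 h, -1.34 at 24 h) and the cyclin CCNA2 (-1.31 at 24 h). Camera called this list at each time too (adjusted p = 5.27e-08, 7.77e-08, 2.23e-05 and 2.76e-08), which was lost with the correlation taken from the data (adjusted p = 0.456, 0.709, 0.742 and 0.498 with an estimated correlation). Within slides its median was -1.03 to 0.10 at 0 h, lower on 3 of 4 slides.

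Some known glucocorticoid-induced genes were higher in siHic5_2 cells that had received no hormone. Of 29 measured, 10 were higher and 1 lower at 0 h (12 and 2 adjusted over the list alone), with a median of 0.40 and within-slide medians of 0.36 to 0.44. TSC22D3 (GILZ, an anti-inflammatory leucine zipper protein) was higher by 1.67 (SE 0.15), by 0.15 to 1.79 over its 3 probes. TNFAIP3, an NF-kappa-B inhibitor, was higher by 1.68, RGS2 by 1.38 and the transcription factor ZBTB16 at least 1.95-fold. Camera called the list at 0 h (adjusted p = 0.00167), and it was lost with the correlation taken from the data (adjusted p = 0.456 with an estimated correlation). At 2 h 0 were higher and 5 lower (the same counts adjusted over the list alone), among them GADD45B (-1.78), PDK4 (-1.26) and the MAP kinase phosphatase DUSP1 (-0.92). At 4 h 1 was higher and 8 lower, KLF9 (-0.95) and ERRFI1 (-0.88) among the latter. By 24 h 4 were higher, such as RASD1 (at least 2.02-fold), and 5 lower, such as the sodium channel subunit SCNN1A (-1.40). Counts at 4 and 24 h were the same adjusted over the list alone. The list as a whole was not called at these times (camera adjusted p = 0.175, 0.23 and 0.928); at 24 h its median was 0.07 and its mean 0.05 while camera's direction was down.

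At 24 h, 11 of 19 ATF4 and unfolded protein response genes were higher and 0 lower (12 and 1 adjusted over the list alone), such as the stress transcription factor ATF3 (2.37), the serine synthesis enzyme PSAT1 (2.11) and asparagine synthetase ASNS (1.25). Camera called the list (adjusted p = 0.00281, and adjusted p = 0.498 with an estimated correlation). At 0, 2 and 4 h 6, 9 and 6 were higher and 1, 2 and 0 lower (7, 9 and 6 and 2, 3 and 0 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0977, 0.229 and 0.18). The number of lists that camera called for the knockdown was no larger than other divisions of the same arrays give, and for each called list other divisions gave a camera p as small, except for p53 targets at 2 h.

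The remaining lists were not called for the knockdown at any time. Of 33 focal adhesion genes 5, 5, 12 and 9 were higher and 1, 2, 1 and 7 lower at 0, 2, 4 and 24 h (3, 5, 12 and 9 and 1, 2, 1 and 7 adjusted over the list alone; camera adjusted p = 0.165, 0.516, 0.0944 and 0.928), with ITGA2 at 0, 2 and 4 h and ITGA5 (1.47 at 24 h) against FERMT2 and ITGA1 (at least 3.46-fold lower at 24 h). The list's 24 h median was 0.08, its mean -0.05 and camera's direction down. Inflammatory and AP-1 genes had 3, 3, 3 and 5 of 17 higher and 1, 0, 0 and 0 lower (3, 2, 3 and 5 and 1, 0, 0 and 0 adjusted over the list alone), including MMP3 at 0, 2 and 4 h, FOSL1 (at least 3.29-fold at 24 h) and PLAUR (1.51 at 24 h, probes 0.08 to 1.52). The chemokine CCL2 was higher by 2.31 at 4 h (limma adjusted p = 0.0107), a call lost without siHic5_2 4 h replicate 4. TGF-beta/SMAD targets had 5, 8, 6 and 9 of 21 higher and 2, 2, 4 and 2 lower (5, 8, 7 and 9 and 3, 5, 5 and 3 adjusted over the list alone). Members TGFB2 and siRNA target TGFB1I1 were lower at each time, ID2 (2.19) and ID3 (1.66) higher at 24 h. Their median and mean had opposite signs at 2 h (0.15 and -0.07) and 4 h (0.05 and -0.28). Extracellular matrix and osteoblast genes had 5, 5, 4 and 3 of 19 higher and 3, 2, 3 and 4 lower (7, 5, 5 and 3 and 3, 2, 3 and 4 adjusted over the list alone), with BMP2 higher (1.85 at 0 h) and COL3A1 lower; median and mean differed in sign at 0 h (-0.03 and 0.02) and 4 h (0.06 and -0.07). SRF/YAP and contractile genes had 2, 3, 3 and 4 of 21 higher, ACTA2 among them at each time, and 2, 3, 5 and 2 lower, such as CNN2 (-1.22 at 24 h), with a median of -0.04 and a mean of 0.11 at 0 h and of -0.07 and 0.01 at 2 h. Counts were the same adjusted over the list alone, and the 24 h median and mean were 0.07 and 0.08 with camera's direction down.

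For the smaller groups the counts at 0 and 24 h describe the knockdown, with those adjusted over the list alone in parentheses, higher then lower at 0 h and at 24 h. Hypoxia and glycolysis genes had 2 and 4 of 16 higher and 0 and 1 lower (1 and 0, 4 and 1), with adrenomedullin ADM (1.75) and VEGFA (1.16) higher at 24 h. Metallothioneins had 3 and 2 of 6 higher and 0 lower (3 and 1, 2 and 0), including MT1G (2.13 at 0 h) and MT1H (at least 1.36-fold at 24 h). Cholesterol synthesis genes had 3 and 4 of 17 higher and 1 lower at each time (1 and 1, 7 and 1), with SC5D higher by 1.26 at 0 h. Circadian clock genes had 4 and 2 of 15 higher and 2 lower at each time (4 and 3, 2 and 2). At 0 h NPAS2 was at least 1.49-fold higher and BHLHE41 at least 2.26-fold lower, and the list's median was -0.01 and its mean 0.06. Receptor coregulators had 3 of 19 higher and 1 lower at each time (3 and 1, 2 and 0). At 0 h PPARGC1A was at least 2.47-fold higher, NR3C2, the mineralocorticoid receptor, differed by -0.90, and the list's median was -0.01 and its mean 0.17. Wnt targets had 3 and 1 of 8 higher and 1 lower at each time (3 and 1, 2 and 1). Interferon response genes had 3 and 1 of 17 higher and 2 and 0 lower (3 and 2, 1 and 0), with a median of -0.07, a mean of 0.01 and camera's direction down at 24 h. Ribosomal protein genes had 0 of 20 higher and 1 and 3 lower (0 and 0, 0 and 3), such as RPL13A (-0.67 at 24 h). Reference genes had 1 and 2 of 10 higher and 1 lower at each time (1 and 1, 2 and 1), GUSB by -0.84 at 24 h. Of 5 epithelial markers 0 were higher and 1 lower at each time (0 and 1, 0 and 0), ELF3 by -1.55 at 0 h, and at 24 h their median was -0.02, their mean 0.08 and camera's direction down. Of 3 blood cell markers 0 moved in either direction (0 and 0, 0 and 0). Of 4 endothelial markers 0 were higher and 1 lower (0 and 1, 0 and 1), the VEGF receptor KDR at least 1.72-fold at 24 h (median 0.08, mean -0.40). At 24 h camera adjusted p-values were 0.11 for cholesterol synthesis and 0.16 for hypoxia, and higher for the others in this paragraph.

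Dexamethasone raised well known target genes in siNS cells within 2 h. PDK4, which inhibits pyruvate oxidation, was at least 64.9-fold higher and KCNA5 at least 19.7-fold. TXNIP rose by 5.04 (SE 0.30), TIPARP by 4.66 (0.20), PHACTR3 by 3.95 (0.39; probes 2.83 to 3.95), MSX2 by 3.56, TSC22D3 by 3.17 (0.15), tissue factor F3 by 3.16 and RGS2 by 2.92. Among the genes that fell most were IER3 (-3.28, SE 0.29), the EGF family ligand HBEGF (-3.16), IL11 (-2.63), the kinase PIM1 (-2.54), LIF (-2.45), BCL3 (-2.16) and HES1 (-2.13), and SOCS3 was at least 2.58-fold lower. At 4 h KLF15 was at least 5.06-fold higher and FKBP5, a receptor chaperone component, rose by 1.39, while CCL2 (-4.65), the chemokine CXCL8 (-3.15, probes -4.62 to -3.15) and IRS1 (-3.18) fell. By 24 h PHACTR3 (6.66), CIDEC (5.72), GREB1 (5.52), NKD1 (5.51) and the growth hormone receptor GHR (4.77) were the largest rises by each gene's brightest probe among genes above background in both groups, but GREB1 rose by 0.47 to 5.52 over 3 probes and CIDEC by 1.38 to 5.72 over 2. PNLIP was at least 178-fold, SPINK13 at least 159-fold and PDK4 at least 101-fold higher. At that time CCL2 (-6.71), HBEGF (-4.99), EMP1 (-4.83) and IER3 (-4.49) fell, and TGFBI and CLDN1 were at least 21.2 and 14.6-fold lower. Limma adjusted p-values for the genes in this paragraph were at most 8.3e-05, that of CXCL8 at 4 h.

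Of the genes fixed as hormone markers, TSC22D3 rose by 3.17, 3.50 and 4.49 at 2, 4 and 24 h in siNS (1.05 to 3.32, 2.30 to 3.92 and 3.45 to 4.96 over 3 probes), NFKBIA by 1.98, 1.79 and 1.93, SGK1 by 1.65, 1.68 and 1.75 and CEBPD by 0.99, 1.05 and 2.32. FKBP5 changed by 0.59 (limma adjusted p = 0.0199, not called without siNS 0 h replicate 1 or 3 or 2 h replicate 2 or 4), 1.39 and 2.69. DUSP1 differed by 0.61, 0.71 and 1.26 (limma adjusted p = 0.0627, 0.0146 and 1.57e-06), the 4 h call ending without siNS 0 h replicate 2 or 4 h replicate 1. KLF9 differed by 0.61 and 0.65 at 2 and 4 h and rose 2.83-fold at 24 h (limma adjusted p = 0.187, 0.105 and 3.38e-06), and ZBTB16, not above background at 0 h, was at least 1.87 and 5.56-fold higher at 4 and 24 h (limma adjusted p = 0.321 at 2 h, 0.0022 and 7.45e-10). The ZBTB16 call at 4 h ended when only the 2 groups compared were fitted or number 1 was left out, and its 3 probes disagreed in sign at 2 h. PER1, not above background at 0 h, was at least 1.67-fold higher at 2 h and 1.37-fold at 24 h (limma adjusted p = 0.0188, and 0.0166 at 24 h; 0.349 at 4 h), and its calls ended without siNS 0 h replicate 1 or 2 or 2 h replicate 1 at 2 h and without 0 h replicate 2 at 24 h. At 2 h CCL2 differed by -2.98 and CXCL8 by -2.22 (limma adjusted p = 0.00532 and 0.0127), and neither was called with the slide as a block or with NI arrays in place of siNS. The CXCL8 call also ended without siNS 0 h replicate 1 or 4 or 2 h replicate 2. IL6 was above background on 1 array at 0 h and on 0 at 2, 4 and 24 h, so that no size is given (limma adjusted p = 0.274, 0.153 and 0.0308). The IL6 call at 24 h ended without siNS 0 h replicate 1 or 4 or 24 h replicate 2 or 3, or with the slide as a block. NR3C1 differed by -0.71, -1.15 and -0.53 (limma adjusted p = 0.0743, 0.000478 and 0.0685), and TGFB1I1 by -0.26, -0.09 and -1.06 (limma adjusted p = 0.725, 0.98 and 0.000569). PXN differed by 0.66, 0.69 and 0.25 (limma adjusted p = 0.0625, 0.0294 and 0.378), with the 4 h call lost without siNS 0 h replicate 1, 3 or 4 or 4 h replicate 1 or 4. LPXN differed by -0.32, -0.34 and -1.47 (limma adjusted p = 0.895, 0.942 and 0.034), with the 24 h call lost without siNS 0 h replicate 3 or 24 h replicate 1, 2 or 4. NI in place of siNS also ended the calls of FKBP5 at 2 h, PER1 at 2 and 24 h, DUSP1 and PXN at 4 h and LPXN at 24 h. With the replicate number as a block DUSP1 at 2 h and KLF9 at 4 h were called as well (limma adjusted p = 0.00579 and 0.0335).

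Limma called 574 genes at 2 h in siNS (246 up, 328 down), 974 at 4 h (509 and 465) and 4709 at 24 h (2337 and 2372). In NI cells the totals were 353, 1048 and 4667. With the slide as a block they were 327 (186 up, 141 down), 914 and 4757, and with the replicate number as a block within each transfection state 1148 at 2 h and 1553 at 4 h. No slide held both siNS groups of the 2 h contrast.

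Of 29 glucocorticoid-induced genes 16, 18 and 21 rose in siNS at 2, 4 and 24 h and 1, 1 and 3 fell (21, 21 and 24 up adjusted over the list alone; 1, 1 and 3 down). Camera called the list at each time (adjusted p = 4.05e-34, 1.29e-32 and 1.7e-14), also with the correlation taken from the data (adjusted p = 4.64e-06, 7.23e-06 and 0.00442 with an estimated correlation). Within-slide medians were 1.19 to 1.23 at 4 h and 1.62 to 1.99 at 24 h. Of 17 inflammatory and AP-1 genes 7, 9 and 13 fell and 0, 1 and 0 rose (8, 10 and 14 down and 1, 1 and 0 up adjusted over the list alone), with IER3, LIF and CCL2 in front (camera adjusted p = 1.17e-07, 1.74e-07 and 7.46e-07; adjusted p = 0.0403, 0.0441 and 0.0926 with an estimated correlation). Of 21 TGF-beta/SMAD targets 7, 9 and 12 fell and 2, 1 and 2 rose (10, 11 and 13 down and 2, 1 and 2 up adjusted over the list alone), such as SMAD7 (-1.79 at 2 h), PMEPA1 (-1.74 at 4 h) and TGFB2 (-3.25 at 24 h). Camera adjusted p-values for that list were 8.48e-06, 3.21e-06 and 0.000639, against adjusted p = 0.0403, 0.0369 and 0.159 with an estimated correlation. At 24 h 15 of 29 cell cycle genes fell (17 adjusted over the list alone), such as the replication helicase subunits MCM2 (-1.81) and MCM5 (-1.35), with camera adjusted p = 2.09e-05 and adjusted p = 0.475 with an estimated correlation.

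Other genes moved at 24 h in lists that were not called. SESN1 rose by 4.12 and COL6A1 by 3.36, USP18, ITGA1 and KDR were at least 4.66, 3.58 and 1.78-fold higher, while contractile CNN1 (-3.67), the matrix protein THBS1 (-2.48), the adaptor BCAR1 (-2.00) and the hematopoietic marker CD34 (-1.87) fell. Limma adjusted p-values were at most 2.96e-08, that of CD34.

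In siHic5_2 cells the hormone acted on many of these genes. At 2 h PDK4 rose by 4.18 (SE 0.29), KCNA5 by 4.12 (0.29), TXNIP by 3.73, TIPARP by 3.54, ARC by 3.35, SHISA2 by 3.09 and CRISPLD2 by 2.47. The inhibitors of differentiation ID1 (-2.96) and ID3 (-2.52) fell, as did HES1 (-2.82), PIM1 (-2.79), IER3 (-2.74) and endothelin EDN1 (-2.55), and IL11 was at least 6.2-fold lower. At 4 h LAD1 (4.61, probes 1.20 to 4.61), PDK4 (4.38) and CRISPLD2 (4.07) led, against EDN1 (-3.85), CCL20 (-3.97), CCL2 (-3.12) and CXCL8 (-3.06, probes -4.67 to -3.06). At 24 h PDK4 rose by 6.12, DNER by 5.80, TXNIP by 5.38, CRISPLD2 by 4.96, SLN by 4.48 and the estrogen receptor GPER1 by 4.41 (probes 2.51 to 4.49), and PNLIP was at least 131-fold higher. CCL2 (-6.25), SFTA1P (-4.50), CCL20 (-4.25), EMP1 (-3.99) and the chemokine CX3CL1 (-3.94) fell, and MYEOV was at least 20.6-fold lower. Limma adjusted p-values for these genes were at most 0.00148, that of CCL2 at 4 h.

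Of the fixed markers in siHic5_2, TSC22D3 rose by 1.32, 1.60 and 2.81 at 2, 4 and 24 h, NFKBIA by 1.08, 1.06 and 1.21 and SGK1 by 0.90, 0.89 and 1.46. FKBP5 differed by 0.00, 0.18 and 1.33 (limma adjusted p = 1, 0.584 and 8.31e-09), and CEBPD by 0.50, 1.05 and 2.08 (limma adjusted p = 0.204, 4.9e-05 and 3.02e-12). DUSP1 fell by 1.24 at 2 h and fell by 1.00 at 4 h (limma adjusted p = 2.66e-05 and 0.000273) and differed by 0.20 at 24 h (0.478). KLF9 differed by -0.31, -0.90 and 0.87 (limma adjusted p = 0.898, 0.0106 and 0.00484), the 4 h call ending without siHic5_2 4 h replicate 2. ZBTB16 differed by -0.16, -0.15 and 0.77 (limma adjusted p = 1, 0.862 and 0.0696), its probes disagreeing in sign at 4 and 24 h, and PER1 by 0.35, 0.56 and 0.68 (limma adjusted p = 0.975, 0.387 and 0.148). At 2 h CXCL8 differed by -2.75 (limma adjusted p = 0.0016, not called when only the groups compared were fitted) and CCL2 by -1.95 (0.173); at 24 h CXCL8 fell by 3.32 (probes -5.07 to -3.32). IL6 was lower at 4 and 24 h, where it was above background on 0 arrays and no size is given (limma adjusted p = 0.0436 and 0.00484; 0.57 at 2 h), with calls that ended without siHic5_2 0 h replicate 2 or 3 or 4 h replicate 1, 2 or 4 or with the slide as a block at 4 h, and without 0 h replicate 3 at 24 h. NR3C1 differed by -0.58, -0.94 and -0.27 (limma adjusted p = 0.298, 0.00491 and 0.426), and TGFB1I1 by -0.18 at 2 h (limma adjusted p = 1). TGFB1I1 was at least 1.12-fold lower at 24 h (limma adjusted p = 0.00397, and 0.0545 at 4 h), a call lost without background correction. PXN differed by 0.30, 0.79 and -0.05 (limma adjusted p = 0.848, 0.00875 and 0.891; at 4 h lost without siHic5_2 0 h replicate 2 or when only the groups compared were fitted) and LPXN by -0.02, -0.33 and -2.94 (limma adjusted p = 1, 0.812 and 5.19e-05). With the replicate number as a block CCL2 at 2 h, TGFB1I1 at 4 h and ZBTB16 at 24 h were called as well (limma adjusted p = 0.0397, 0.0277 and 0.0456).

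Limma called 344 genes at 2 h in siHic5_2 (174 up, 170 down), 1323 at 4 h (613 and 710) and 4137 at 24 h (2115 and 2022). With the slide as a block the totals were 301, 1173 and 4256, and with the replicate number as a block within each transfection state 621 at 2 h and 2283 at 4 h.

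Of the glucocorticoid-induced list 10, 13 and 20 rose in siHic5_2 and 3, 4 and 3 fell (12, 14 and 21 up and 3, 4 and 3 down adjusted over the list alone), with within-slide medians of 0.17 to 0.64 at 2 h, 0.64 on 1 slide at 4 h and 1.10 to 1.72 at 24 h. Camera called it at each time (adjusted p = 1.13e-11, 2.42e-08 and 5.62e-12; adjusted p = 0.01, 0.0441 and 0.0134 with an estimated correlation). Inflammatory and AP-1 genes fell in 5, 8 and 13 of 17 cases and rose in 0, 1 and 1 (9, 9 and 13 down and 0, 1 and 2 up adjusted over the list alone; camera adjusted p = 2.19e-09, 4.72e-06 and 3.89e-06, and adjusted p = 0.0167, 0.105 and 0.12 with an estimated correlation). TGF-beta/SMAD targets fell in 6, 13 and 12 of 21 cases and 1 rose at each time (8, 14 and 12 down and 1 up at each time adjusted over the list alone), including SMAD7 (-2.18 at 2 h) and TGFBI (-3.60 at 24 h). That list was called at 2, 4 and 24 h (camera adjusted p = 4.37e-08, 1.71e-09 and 0.00199; adjusted p = 0.01, 0.00586 and 0.12 with an estimated correlation), and its within-slide medians at 24 h were -1.18 to 0.36, lower on 3 of 4 slides.

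At 24 h further lists were called in siHic5_2, all of them lost with an estimated correlation. Cell cycle genes fell in 22 of 29 cases (22 adjusted over the list alone; AURKB by -1.70; camera adjusted p = 2.26e-07, and adjusted p = 0.347 with an estimated correlation). Focal adhesion genes fell in 14 of 33 cases and rose in 5 (15 and 5 adjusted over the list alone), such as ITGA2 (-2.67) and the actin cross-linker ACTN1 (-1.42), with camera adjusted p = 0.00645 and adjusted p = 0.12 with an estimated correlation. SRF/YAP and contractile genes fell in 12 of 21 and rose in 2 (12 and 2 adjusted over the list alone; CNN1 by -2.99), with the same camera adjusted p = 0.00645 and adjusted p = 0.12 with an estimated correlation. Extracellular matrix and osteoblast genes fell in 10 of 19 and rose in 3 (12 and 3 adjusted over the list alone; osteoprotegerin TNFRSF11B by -2.53; camera adjusted p = 0.021, and adjusted p = 0.133 with an estimated correlation). Hypoxia and glycolysis genes rose in 8 of 16 and 0 fell (9 and 1 adjusted over the list alone; NDRG1 by 2.10; camera adjusted p = 0.028, and adjusted p = 0.12 with an estimated correlation). In siNS these 4 lists were not called at 24 h (camera adjusted p = 0.356, 0.0654, 0.142 and 0.247), and of their differences between the states only that of focal adhesion genes was called (camera adjusted p = 0.0362), which was lost with the correlation taken from the data and with the slide as a block (adjusted p = 0.614 with an estimated correlation, 0.0714 with the slide block). With the replicate number as a block SRF/YAP and contractile genes were called at 2 h too (camera adjusted p = 0.0496, without the block 0.0769). The number of called lists for hormone in either state was no larger than other divisions of the same arrays give. No other division gave a camera p as small for the glucocorticoid-induced list at any time in either state, for TGF-beta/SMAD targets at 4 h in either state and for inflammatory and AP-1 genes at 2 h in siHic5_2, and for the remaining called lists others did.

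Whether the hormone response itself differed between siHic5_2 and siNS was tested as an interaction. At 2 h TSC22D3 had a weaker response by -1.85 (SE 0.21, limma adjusted p = 5e-07) and DUSP1 a response lower by -1.85 (SE 0.28, limma adjusted p = 0.000238), from a value of 0.61 in siNS to -1.24. PHACTR3 (-2.92, limma adjusted p = 0.00687), NFKBIA (-0.89, 0.00122), MSX2 (-1.83, 0.00625) and SLC46A3 (-1.53, 0.0085) responded less. PDK4 was called lower too (limma adjusted p = 0.00227), without a size because no siNS array at 0 h had it above background. EDN1 (-2.12), EDN2 (-2.41) and the mTOR inhibitor DDIT4 (-2.46) had lower responses, and TMEM43 (1.14, 0.00122) was the 1 gene with a higher response. Calls of PDK4, PHACTR3, DDIT4 and EDN2 were lost when number 1 was left out of all groups or only the groups compared were fitted, those of NFKBIA and TMEM43 in the latter fit, those of MSX2 and SLC46A3 without number 1, those of PHACTR3 and MSX2 with no background correction, and those of DDIT4, EDN1 and EDN2 with NI in place of siNS. Over its 3 probes the TSC22D3 difference was -1.92 to -0.07 at 2 h, -2.22 to -1.31 at 4 h and -1.87 to -0.39 at 24 h. TCIM, named after its values were seen, was above background in 1 group only, siHic5_2 at 0 h (log2 level 8.77 ± 0.89, SD, n = 4), and was at least 6.15-fold lower there after 2 h of hormone and at least 5.73-fold lower after 4 h, with limma adjusted p-values of 2.56e-10 and 7.86e-11 for its interaction.

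At 4 h PHACTR3 (-3.45, SE 0.56), SLC46A3 (-2.27, 0.30) and TSC22D3 (-1.91, 0.21) responded less. DUSP1 (-1.71, 0.28) and the transcription factor FOXA2 (-1.42, 0.25) had lower responses. DUSP1 had 0.71 in siNS and fell with hormone in siHic5_2, and FOXA2 had 1.03 and -0.39. EDN1 was repressed more (-2.12, SE 0.41), and GRAMD4 (2.02, 0.30) had a higher response. CIDEC, not above background in siHic5_2 at 0 h and with 2 probes of differing sign, was called lower, and the cytokine CSF3, above background in siHic5_2 at 4 h alone among the 4 groups compared, was called higher, at least 1.97-fold over 0 h. Limma adjusted p-values of these 9 genes were at most 0.00568, that of EDN1. FKBP5 (-1.21, limma adjusted p = 0.00381), NFKBIA (-0.73, 0.00819), PDK4 (lower, 0.0095) and SHISA2 (1.52, 0.00764) were called, and all 4 calls were lost when number 1 was left out of all groups. KLF9 differed by -1.55 (limma adjusted p = 0.022), a call lost without siNS 0 h replicate 2 or 3, siNS 4 h replicate 1 or 4, siHic5_2 0 h replicate 1 or siHic5_2 4 h replicate 3.

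At 24 h the difference reached 418 genes. ARC (4.00, SE 0.60), SLCO2A1 (3.85, 0.59), lipoprotein lipase LPL (2.45, 0.48), SHISA2 (2.13), LFNG (2.13, probes 0.45 to 2.13) and GPER1 (2.11, probes 1.35 to 2.37) had higher responses with siHic5_2. TGM2 (-3.74, probes -3.74 to -1.35), PHACTR3 (-3.34), DCLK1 (-2.93, probes -2.93 to -1.77), EDN1 (-2.85), ITGA2 (-2.64), SESN1 (-2.43), KITLG (-2.16) and the activin antagonist FST (-2.11) had lower ones. TEDDM1, CIDEC, the acute-phase protein SAA1, ACKR2, ZBTB16 and KDR were called lower too, without a size because they were not above background in siNS or siHic5_2 at 0 h. TEDDM1 was at least 53.8-fold higher after hormone in siNS and at least 1.36-fold in siHic5_2, CIDEC rose by 5.72 and at least 1.28-fold, and ACKR2 was at least 9.33-fold higher and differed by 0.10. Of the fixed markers TSC22D3 (-1.67, limma adjusted p = 8.58e-07), FKBP5 (-1.36, 0.000114) and NFKBIA (-0.72, 0.00195) responded less, as did NKD1 (-1.97) and COL6A1 (-1.97). Limma adjusted p-values of these genes were at most 0.00218, that of ZBTB16, and the call of LPL was lost when only the groups compared were fitted. DUSP1 differed by -1.06 (limma adjusted p = 0.0204), a call lost without siNS 0 h replicate 2, siHic5_2 0 h replicate 3 or siHic5_2 24 h replicate 2 or 4.

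For the repressed chemokines and cytokine no such difference was called: CCL2 differed by 1.03, 1.53 and 0.46 at 2, 4 and 24 h, and CXCL8, whose probes disagreed in sign at 4 and 24 h, by -0.53, 0.09 and -0.08, with standard errors of 0.99 and 0.81. IL6 was not above background in siNS with hormone, and limma adjusted p-values of all 3 were 0.807 or more. SGK1 differed by -0.74, -0.79 and -0.28 and CEBPD by -0.49, 0.01 and -0.24, neither of them called, nor was PER1, which was not above background in siNS at 0 h (limma adjusted p of 0.15 or more). KLF9 was not called at 2 h (-0.92) or 24 h (-0.63, limma adjusted p = 0.409), nor ZBTB16 at 2 h or 4 h (limma adjusted p = 0.123 at 4 h). FKBP5 at 2 h differed by -0.59 (limma adjusted p = 0.907). PXN, LPXN and NR3C1 differed by -0.30, -1.47 and 0.27 at 24 h (limma adjusted p = 0.749, 0.398 and 0.818), and TGFB1I1, not above background in siHic5_2, was not called (0.909).

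The limma interaction totals were 16 genes at 2 h (1 higher, 15 lower), 54 at 4 h (16 and 38) and 418 at 24 h (195 and 223). With the slide as a block they were 13, 67 and 436, of which 43 at 4 h and 386 at 24 h were also called without it. Within slides 100% of the called genes had the same sign at 4 h (1 slide) and 97.8 to 100% at 24 h (3 slides), on the arrays they were called on, against 73.7 and 65 to 71.2% of the others. With the replicate number as a block they were 24, 115 and 683, and with that block within each transfection state 47, 213 and 1177. Leaving out siNS 4 h replicate 1 gave 32 genes at 4 h and leaving out siNS 4 h replicate 3 gave 86. Of the 418 genes at 24 h, 193 responded in the same direction in siNS and siHic5_2 and 27 in opposite directions. Another 111 responded in siNS but not in siHic5_2 (52 rose, 59 fell), whatever their call in NI. In siHic5_2 but neither control 75 responded (42 rose, 33 fell), and in siHic5_2 and NI but not siNS 12 did. At 0 h only 113 of the 418 genes differed between siHic5_2 and siNS, at 24 h only 237 did, 66 did at both times and 2 at neither. At 2 h, 7 of the 16 differed at 0 h only, 1 with hormone only and 8 at both.

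The smaller TSC22D3 response started from a higher level. That level was 7.90 ± 0.38, 11.08 ± 0.03, 11.41 ± 0.10 and 12.39 ± 0.17 at 0, 2, 4 and 24 h in siNS, 7.99 ± 0.25, 10.94 ± 0.26, 11.33 ± 0.19 and 12.31 ± 0.09 in NI and 9.58 ± 0.33, 10.90 ± 0.17, 11.18 ± 0.11 and 12.39 ± 0.10 in siHic5_2 (log2, SD, n = 4 each).

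Genes chosen by their response in NI arrays responded less with siHic5_2 than with siNS. Of 353 such genes at 2 h 10 were called weaker and 1 stronger, of 1048 at 4 h 23 and 13, and of 4667 at 24 h 261 and 60. The median of the interaction, signed so that a weaker response is negative, was -0.289, -0.222 and -0.202, and 74.5, 69.3 and 71.6% of the genes lay below 0. Within slides the median was -0.173 at 4 h (1 slide) and -0.306 to -0.119 at 24 h (3 slides). Median response sizes at 24 h were 0.81 in NI, 0.79 in siNS and 0.60 in siHic5_2. Medians were -0.357, -0.274 and -0.200 for induced genes and -0.221, -0.166 and -0.205 for repressed ones. Of the genes called weaker 10, 23 and 150 were induced and 0, 0 and 111 repressed, and of those called stronger 1, 10 and 34 were induced and 0, 3 and 26 repressed. The difference between induced and repressed genes was not tested. With no interaction, simulation gave medians of -0.025, -0.009 and 0.001 for this choice of genes, and of -0.010, -0.013 and -0.010 when same-numbered arrays were correlated as measured. The result depends on that choice: genes chosen in siHic5_2 arrays had medians of 0.169, 0.289 and 0.071, where simulation gave 0.024, 0.038 and 0.042, and 0.024, 0.026 and 0.020 with correlated arrays. Among the genes called stronger at 24 h were EDN1 (-2.85), CD93, HTRA4, GPR83 and the signalling adaptor TRAF1. With siHic5_2 CD93, HTRA4 and GPR83 were at least 7.23, 13.9 and 5.69-fold higher after hormone and TRAF1 at least 5.57-fold lower, while in siNS CD93 was not above background at 0 or 24 h, HTRA4 differed by 1.08, GPR83 was at least 1.51-fold higher and TRAF1 at least 1.14-fold lower.

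**Figure D2:**
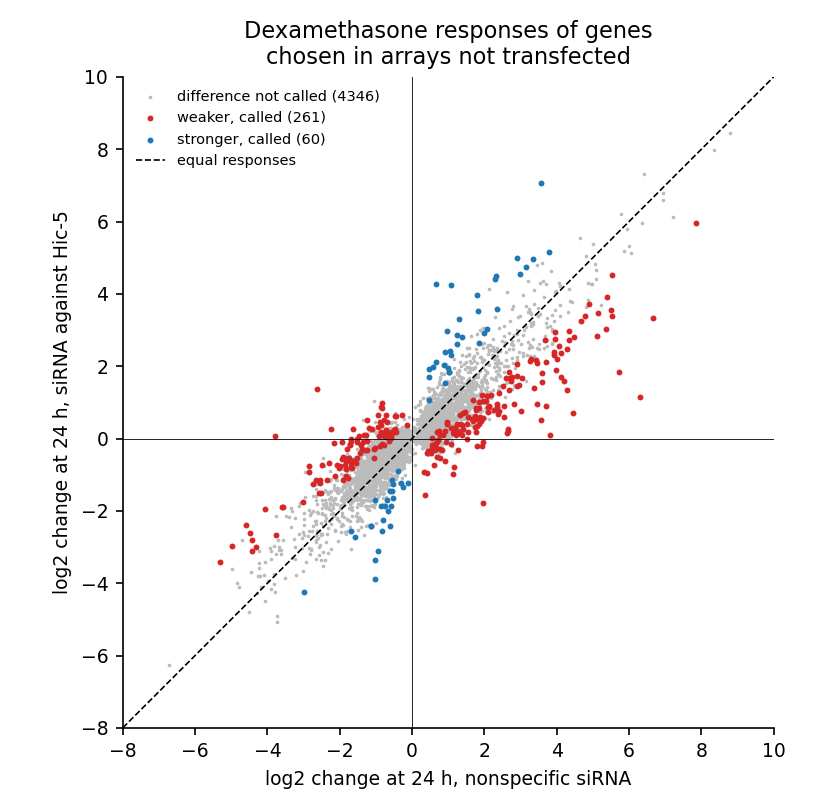
Log2 response to 24 h of dexamethasone in siHic5_2 (vertical) against siNS (horizontal) for the 4667 genes chosen in NI arrays, with the line of equal responses. Coloured points are genes with a called interaction, 261 weaker and 60 stronger with siHic5_2.

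By list, glucocorticoid-induced genes differed in their response at 2 and 4 h, and at 24 h the call did not hold with the correlation taken from the data. Their median interaction was -0.70, -0.62 and -0.51 at 2, 4 and 24 h. Of 29 genes 4, 8 and 8 had lower responses and 0, 0 and 3 higher (11, 13 and 11 lower and 0, 1 and 4 higher adjusted over the list alone). Camera called the list at each time (adjusted p = 1.14e-23, 1.24e-14 and 0.000189), and with the correlation taken from the data at 2 and 4 h but not 24 h (adjusted p = 0.000129, 0.00416 and 0.614 with an estimated correlation). At 24 h other divisions of the same arrays gave a camera p as small. The 3 with higher responses at 24 h included CAVIN2 (1.98), not called when only the groups compared were fitted, and RASD1, at least 2.05-fold higher after hormone in siHic5_2 and not above background in siNS at 0 or 24 h. At 24 h camera also called focal adhesion genes, 6 of 33 with lower responses (7 adjusted over the list alone), such as caveolin CAV1 (-1.35) and ITGA1, above background in siNS at 24 h alone among the groups compared, and p53 targets, 2 of 18 lower (2 adjusted over the list alone), SESN1 and GDF15, the latter above background in siHic5_2 at 0 h alone. For both the adjusted p was 0.0362, lost with the correlation taken from the data (adjusted p = 0.614 and 0.777 with an estimated correlation) and with the slide as a block (camera adjusted p = 0.0714 and 0.0948). The focal adhesion median was -0.02 and its mean -0.27, and the p53 median was -0.15 and its mean -0.36. Inflammatory and AP-1 genes were not called at 24 h (2 higher, 1 lower; camera adjusted p = 0.383), nor was any other list. With the slide as a block the medians of the glucocorticoid-induced list were -0.68, -0.54 and -0.53, and of 40 called lists over all contrasts 40 kept the sign of their median, which moved by at most 0.26. Only 1 slide held all groups of the 4 h interaction (median -0.49) and 3 those of the 24 h interaction, with medians of -0.76 to -0.16 for the glucocorticoid-induced list, -0.27 to 0.04 for focal adhesion genes and -0.41 to -0.16 for p53 targets; at 2 h no slide did. The number of lists called for the interaction was no larger than other divisions of the same arrays give.

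**Figure D3:**
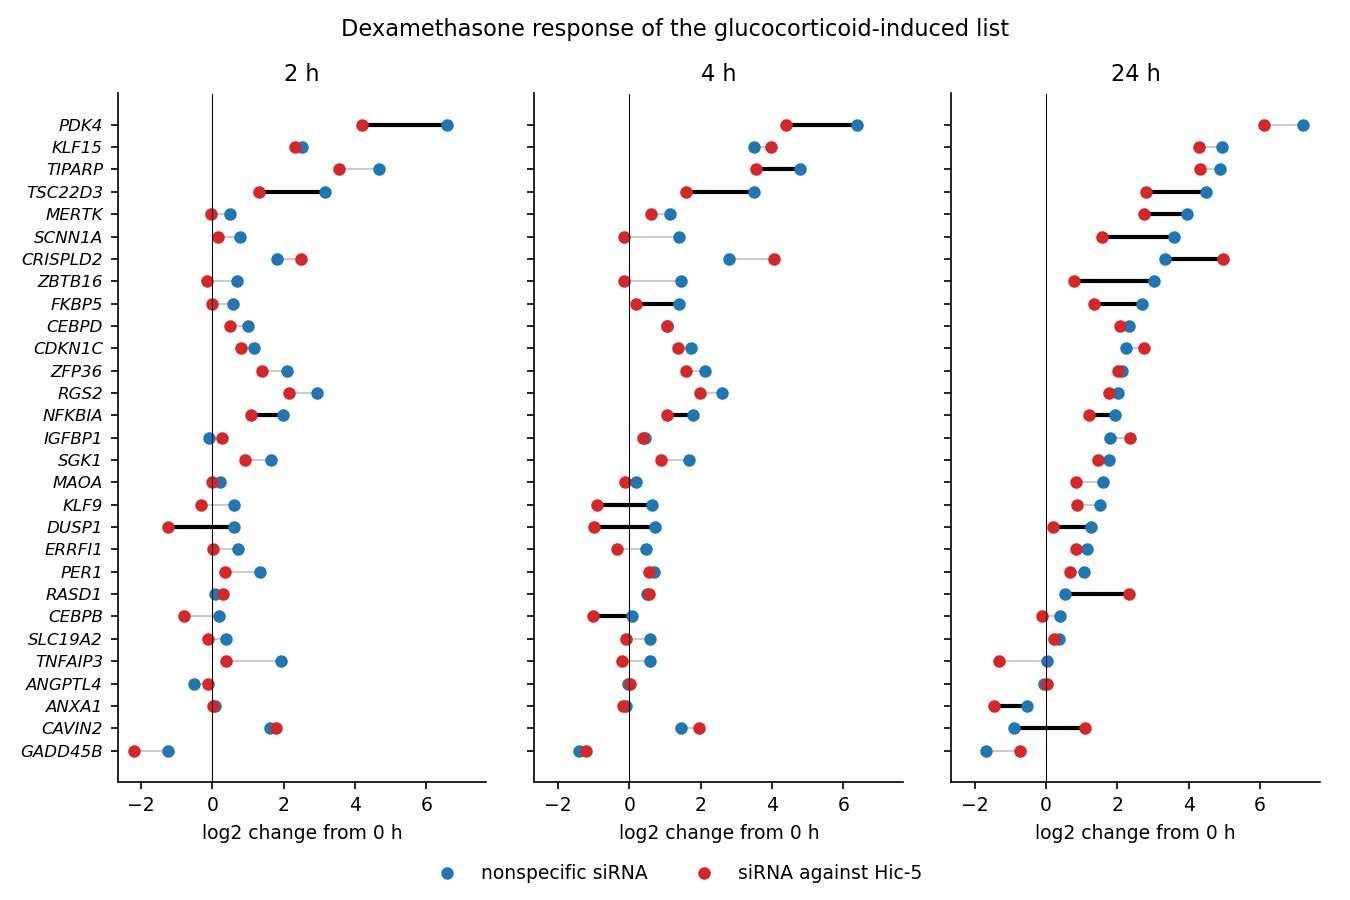
Log2 response of the 29 measured glucocorticoid-induced genes at 2, 4 and 24 h of dexamethasone in siNS and siHic5_2, 1 row per gene, the pair joined by a black line where the interaction was called. The median interaction was -0.70, -0.62 and -0.51, and called lower responses numbered 4, 8 and 8.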

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

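The tests on splits of the arrays for gene counts and for single lists, on number means, the slide block, same-numbered arrays, hormone in the 0 h wells, a shift of all genes, levels before hormone, covariances between different numbers and the spread of responses were chosen after the results were seen; those on the choice of genes, a signal ceiling, splits for weaker responses and splits for the number of called lists were set before.

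By the test of the difference itself, the hormone response differed between siHic5_2 and siNS for 16 genes at 2 h, 54 at 4 h and 418 at 24 h. Camera called the glucocorticoid-induced list too, with a median interaction of -0.70, -0.62 and -0.51 at 2, 4 and 24 h, a call held at 2 and 4 h and lost at 24 h with the correlation taken from the data (adjusted p = 0.000129, 0.00416 and 0.614 with an estimated correlation). Its camera p was reached in 1 of 35 splits, the real one, at 2 h (5.42e-25, smallest other 3.27e-14) and 4 h (5.89e-16 and 1.65e-11), but in 3 of 35 at 24 h (9.01e-06 and 5.12e-07), where chance cannot be excluded. At 24 h camera also called the focal adhesion list, with a median of -0.02, and the p53 target list, with a median of -0.15, both lost with the correlation taken from the data (adjusted p = 0.614 and 0.777 with an estimated correlation) and with the slide as a block (0.0714 and 0.0948), and their camera p was reached in 2 and 5 of 35 splits (0.00518 and 0.00398, smallest other 0.000626 and 0.000463). Among 5008 probes without a single gene symbol, which stood outside the gene tests, limma called 659, 652, 927 and 840 for the knockdown at 0, 2, 4 and 24 h. Between siNS and NI limma called 0 of these probes, with 121 at an unadjusted p under 0.05. On siHic5_2 4 h replicate 2 the TSC22D3 level of 11.01 lay apart from the other 3 arrays (11.21 to 11.26). On siNS 4 h replicate 1 the NR3C1 level of 5.46 lay apart from the other 3 (6.08 to 6.16). These are 2 of 36 groups of 4 arrays examined, where chance alone sets an array apart in about 1 of 20.

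Chance in the grouping of arrays can be excluded for the knockdown: 1 of 35 splits, the real one, gave as many genes at each time, 3078, 3069, 3607 and 3529 at 0, 2, 4 and 24 h, with a highest other split of 339, 577, 1160 and 443. Chance is argued against for the interactions too, with 16, 54 and 418 genes in 1 of 35 splits each and a highest other split of 0, 1 and 10. Hormone arrays are paired by number, and 8 splits part all 4 pairs, too few by themselves for a share under 0.05. Among these the highest other split gave 0, 0 and 503 genes at 2, 4 and 24 h in siNS against 574, 974 and 4709, and 1, 1 and 428 in siHic5_2 against 344, 1323 and 4137. The remaining splits leave pairs on one side and gave at most 12, 38 and 747 in siNS and 20, 280 and 971 in siHic5_2, so that 1 of all 35 splits was as large each time. For the nonspecific siRNA the real count of 0 was reached in 35 of 35 splits, and swapping whole numbers between siNS and NI called up to 3574 genes (median 229.5), which points to a structure of the samples, the numbers that siNS and NI share. For its interactions the real count was 0 and 35 of 35 splits reached it, with a highest other of 0, 0 and 2. Chance cannot be excluded for the number of called lists: knockdown 10 lists, as many in 15 of 35 splits (highest other 21); hormone in siNS 10, in 30 of 100 draws that shuffled the times within numbers (14); hormone in siHic5_2 14, in 20 of 100 (22); interaction 5, in 9 of 35 (7). Nor can it for most single lists of the knockdown, where a camera p as small came in 5, 5, 7 and 11 of 35 splits at 0, 2, 4 and 24 h for cell cycle genes (smallest other 2.89e-16, 1.53e-14, 2.64e-12 and 1.3e-26, real 5.02e-09, 3.7e-09, 1.06e-06 and 1.32e-09), in 3, 1, 3 and 5 for p53 targets, in 3 for the glucocorticoid-induced list at 0 h and in 2 for the ATF4 list at 24 h. For hormone the glucocorticoid-induced list had 1 of 35 at each time in both states, and the other called lists had 1 to 14.

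The siRNA against Hic-5 moved 25.8 to 30.3% of the genes, while limma called 0 for the nonspecific siRNA (189 at an unadjusted p under 0.05). A test on each number's mean over the 4 times argues against spread between experiments. Limma called 4241 genes between siHic5_2 and siNS (highest other of 35 splits 0). The 0 between siNS and NI (72 at an unadjusted p under 0.05) decides nothing, as their shared numbers were not paired. Slide differences are argued against too: with the slide block 98.5, 81.7, 87.9 and 95.7% of called genes remained. The knockdown arrays may still come from other experiments than the control arrays: same-numbered siHic5_2 and siNS arrays correlated at -0.018, against 0.401 for siNS and NI, and this cannot be told apart from the knockdown. The lower Hic-5 level, and effects of the single siRNA on other transcripts, stay open and untested.

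Genes that dexamethasone induced in NI at 24 h were higher before hormone with the siRNA against Hic-5, by a median of 0.138 (0.104 to 0.194 on single arrays) over all 2210 genes, 543 called higher and 197 lower, and of 0.144 (0.083 to 0.254) over the 143 induced 8-fold or more, 32 called higher and 4 lower. A shift of all genes on those arrays is argued against, since induced genes lay above repressed ones by 0.137 to 0.320 on each of the 4 arrays. Traces of hormone in the 0 h knockdown wells could give such a difference and stay open: the 35 genes induced 8-fold or more that were above background in siNS at 0 h had a median of 0.612 (0.492 to 0.612; 16 called higher and 2 lower) against 0.141, 0.228 and 0.112 for those induced less than 2, 2 to 4 and 4 to 8-fold, but over all induced genes these 3 classes had 0.138, 0.159 and 0.082, so that the medians did not grow with the response. Repressed genes do not decide on such traces. By the 24 h response, 75 genes repressed 8-fold or more had a median of -0.081 (-0.334 to -0.004 on single arrays) against -0.103 for those repressed less than 2-fold. By the 2 h response, 11 genes above background repressed 4 to 8-fold had -0.356 (-0.587 to 0.04 on single arrays). Raised target genes without hormone at a low Hic-5 level are the biological alternative, which was not tested apart from such traces.

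Genes chosen by their response in NI arrays responded less with siHic5_2. Called weaker at 2, 4 and 24 h were 10, 23 and 261 genes (10, 23 and 150 of them induced). Each count came in 1 of 35 splits (highest other 0, 0 and 5), which argues against chance. A ratio of covariances with the NI response over all genes, siHic5_2 over siNS, of 0.798 at 24 h (0.767 to 0.811 with 1 number left out; 0.803 between different numbers) does not by itself settle the choice of genes, because it weights genes by their NI response and genes chosen in siHic5_2 arrays had a median of 0.071, but among genes whose highest group mean was 8 to 10 the same ratio, 0.814 (0.784 to 0.833), argues against a ceiling of the signal. Levels before hormone as the whole cause are argued against because at 24 h the knockdown effect, signed by the NI response, was still -0.074 (-0.108 to -0.038 on single arrays). At 24 h a different response of equal size as the whole cause, and the choice of genes, are argued against by the spread of responses over all genes, which uses no choice. That spread was 0.906 of that in siNS (0.875 to 0.931 with 1 number left out) and 0.921 of that in NI (0.9 to 0.944). At 2 h it was 0.835 of that in siNS (0.796 to 0.884) and 0.959 of that in NI (0.927 to 0.992). The controls themselves differed at 2 h, with spreads of 0.353 in siNS and 0.308 in NI against 0.295 in siHic5_2. Among genes whose highest group mean was 8 to 10 the 2 h spread was 1.01 of that in NI (0.974 to 1.06). At 2 h, and at 4 h with 1.03 of siNS (0.98 to 1.07), a response of equal size therefore cannot be told apart from a weaker one. A weaker hormone response at a low Hic-5 level goes with the ratio at 24 h as a hypothesis. Hormone in the 0 h wells, which would act through the levels before hormone, stays open. At 24 h it does so for a part of the pattern only, by the medians above the larger part.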

How the results depend on the processing

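Chosen after seeing the data were direct negative controls, the replicate block within states, omission of number 1 and genes chosen in siHic5_2 arrays. Over all alternatives, 24263 results of named genes kept their direction and side of the threshold, 974 lost the call, 50 gained one and 1 reversed; for lists these were 1396, 27, 5 and 0. The 4 contrasts of siNS with NI had 0 limma calls under every alternative, array left out included (189, 223, 120 and 147 genes at an unadjusted p under 0.05 as reported). Array signal limits the rest: 31.7 to 38.3% of probes were above background, the median standard error was 0.202, and simulated changes of 1.5-fold were found in 34% of cases for the 24 h knockdown. Where a result moved below, the cause was not tested, except that settings with fewer arrays have less power by construction.

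With 1 array left out, the knockdown gave 2360 to 3128, 2385 to 3085, 2661 to 3885 and 2827 to 3326 genes at 0, 2, 4 and 24 h. The hormone response gave 397 to 538, 806 to 899 and 4230 to 4448 in siNS and 257 to 322, 1068 to 1411 and 3654 to 3886 in siHic5_2. The interaction gave 13 to 18 and 321 to 497 at 2 and 24 h, and at 4 h 32 (without siNS 4 h replicate 1) to 86 (without siNS 4 h replicate 3). Among genes chosen in NI, weaker responses at 4 h numbered 15 to 40 without the same arrays, and stronger ones at 2 h 0 to 1.

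For hormone at 2 h in siNS the count of 574 became 327 with the slide block (56.9% of them up, against 42.9%), 327 with only the groups compared, 353 with NI in place of siNS and 366 without number 1. SREBF2 in siNS at 24 h went from -0.66 to 0.01 with NI in place of siNS. Without number 1 the interaction gave 9 genes at 2 h and 29 at 4 h. Camera called 40 of 357 list tests, 15 with an estimated correlation, 39 with the slide block (38 shared), 40 with the authors' values (40 shared) and 44 with the replicate block (40 shared).

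The replicate block, applied over all groups, gave 115 interactions at 4 h and 683 at 24 h, and with the slide block added 25, 176 and 770 at 2, 4 and 24 h. Within each transfection state the replicate block gave 1148 and 1553 genes for hormone at 2 and 4 h in siNS, 621 and 2283 in siHic5_2, and 47, 213 and 1177 interactions. Replicate numbers did not pair siHic5_2 with siNS arrays (correlations of -0.177 to 0.107; 0, 1, 1 and 1 of 4 arrays correlated best with their own number at 0, 2, 4 and 24 h), and with the block the knockdown gave 3772, 3725, 4345 and 4122 genes and camera called the ATF4 list at 0 h (0.0393) and the cholesterol list at 24 h (0.0402). Beyond these and the block values given in the results, the replicate block over all groups changed no other call of a named gene or list.

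For genes chosen in NI arrays the medians with no background correction were -0.203, -0.153 and -0.146 at 2, 4 and 24 h. At 2 h stronger responses numbered 2 with scaling to the median, 0 with no filter, 0 with the slide block and 2 with the replicate block. Weaker and stronger responses at 2 h were 17 and 2 with the replicate and slide blocks, 6 and 0 with only the groups compared, 23 and 5 with the replicate block within each state, and 3 and 0 without number 1. At 4 h they were 52 and 22 with the replicate block, 69 and 32 with both blocks, 89 and 39 within each state, and 13 and 3 without number 1; array weights gave 37 weaker and a stricter filter 8 stronger. At 24 h they were 425 and 101 with the replicate block, 482 and 114 with both blocks, and 726 and 186 within each state. Genes chosen in siHic5_2 arrays reversed the median to 0.169, 0.289 and 0.071 (0.024, 0.038 and 0.042 in simulation with no interaction), with 4 and 6, 13 and 33, and 136 and 171 weaker and stronger.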

Other observations

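Clock genes moved in both directions with 24 h of dexamethasone. In siNS 5 of 15 measured rose and 6 fell (6 and 6 adjusted over the list alone), with the repressor CRY2 (1.34, SE 0.18) and NFIL3 (1.49, SE 0.17) up and BHLHE41 at least 2.23-fold lower; in siHic5_2 5 rose and 4 fell (5 and 4 adjusted over the list alone), with NFIL3 (1.14) up and PER2 (-0.97) and PER3 (-1.09) down. Limma adjusted p-values of these genes were at most 0.00013, and camera did not call the list in either state (adjusted p = 0.944 and 0.947). Its median and mean differed in sign, 0.37 and -0.01 in siNS and -0.14 and 0.05 in siHic5_2. Receptor coregulators rose in 7 and fell in 4 of 19 cases in siNS (8 and 5 adjusted over the list alone; camera adjusted p = 0.562), with the coactivator CALCOCO1 (2.02, SE 0.33) up and the mineralocorticoid receptor NR3C2 (-1.13, SE 0.19) down, and in siHic5_2 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.404), with the chromatin remodelling ATPase SMARCA2 (1.12, SE 0.13) up.

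At 24 h, of 19 ATF4 and unfolded protein response genes 8 fell and 1 rose in siNS (8 and 2 adjusted over the list alone; camera adjusted p = 0.133), such as PSAT1 (-2.23, SE 0.37), ATF3 (-1.74, SE 0.38) and ASNS (-1.47, SE 0.23), and 5 fell in siHic5_2 (5 adjusted over the list alone; camera adjusted p = 0.404), where PSAT1 differed by -1.13. Of 8 Wnt targets 4 fell in siNS and 5 in siHic5_2 (4 and 5 adjusted over the list alone), among them the cyclin CCND1 (-0.95 and -1.15), while NKD1, a Wnt antagonist, rose by 5.51 and 3.54 (camera adjusted p = 0.356 and 0.236); in siNS the median was -0.60 and the mean 0.15. The metallothionein MT1X rose by 1.66 in siNS and 0.94 in siHic5_2, 2 and 3 of the 6 genes of its list rising (the same adjusted over the list alone; camera adjusted p = 0.133 and 0.0985). The cholesterol synthesis enzyme NSDHL rose by 2.20 and 2.31. Limma adjusted p-values of the genes in this paragraph were at most 0.000255 except for PSAT1 in siHic5_2 (0.0144), and of these genes limma called a different response between the states for NKD1 alone (-1.97, limma adjusted p = 0.000708).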
